A study of Mus musculus with 12 samples.

How the data were processed

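RNA was sequenced from cultured cells of 1 B cell lymphoma that had arisen in a C57BL/6 mouse carrying a Myc transgene driven by the Eµ immunoglobulin heavy chain enhancer and a second transgene, Eµ-rtTA. Per the labels, the lymphoma had been transduced either with an empty retrovirus that gives puromycin resistance or with the same kind of virus carrying TFEB fused to ERT2, a mutated ligand-binding domain of the human estrogen receptor. TFEB is a transcription factor of lysosome and autophagy genes, and this form has an alanine in place of a serine through which mTORC1 is known to keep TFEB in the cytoplasm. 4-hydroxytamoxifen (4-OHT) is the ligand that activates ERT2 fusions. Cells of each line received vehicle or 4-OHT for 4 days, with 3 replicates in each of 4 groups and 12 libraries in all. Per the labels' protocols the dose was 250 nM, whereas the series' design text gives the same figure in ng/mL, so the dose is uncertain. The labels do not say whether replicates were separate transductions, separate cultures or repeats of 1 culture, so the p-values measure only the spread between these samples.

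The deposited values are a signal per gene and library that is never negative: normalized read counts, made by the authors by dividing each library's gene read counts by 1 size factor. Per the submitters' processing notes, STAR 2.5.3, HTSeq 0.6.1, DESeq2 1.6.3 and the mouse build mm10 were used. The role of each tool, the gene annotation, any filter and whether reads were counted by strand are not given in the sources used here. RNA was total RNA, and libraries were made with a NuGEN Ovation mouse kit, per the labels' protocols. In every library 100% of the values above 0 were whole multiples, within 0.001, of the smallest value, which is the value of 1 read. Whole reads could therefore be recovered, and the libraries held 11849029 to 22109283 of them. A gene at 0 in a library could have had up to 3 reads, which is 2.21 to 4.15 normalized counts depending on the library. Floors and intervals cover counting error only, since reads copied by PCR are not independent molecules. Between libraries of the same group, the chi-square per degree of freedom over genes with at least 40 reads in sum was 7.88 to 25.5, so the spread exceeded counting error.

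Of 23479 genes, 1395 were at 0 in every library, and 13111 had a value of at least 10 in at least 3 libraries and were tested. Values were taken to log2 after adding a pseudocount of 1, so fold changes are on the log2(value + 1) scale. For low genes they can understate or overstate a change. limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with 1 mean per group, 8 residual degrees of freedom and a prior variance with a trend on mean expression. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. The 5 comparisons were 4-OHT against vehicle in TFEB cells, the same in vector cells, the difference between these effects (interaction), and TFEB against vector cells in vehicle and in 4-OHT. The comparisons share libraries, so overlaps between their genes are not given, except in 1 test in the closing section. The same design was also fitted to the whole reads with edgeR 4.0.16 (quasi-likelihood test), which called 3400, 0, 1940, 646 and 3353 genes in those comparisons, and with DESeq2 1.42.0.

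Before the data were examined, 29 gene lists were fixed, with 981 entries, of which 974 were found in the data, 3 of them under an older symbol. They cover lysosome, autophagy, mTORC1, MYC targets, amino acid and energy metabolism, cell cycle and stress responses, B cell state, and markers of other cell types. The 28 lists with at least 5 tested genes were tested with limma's camera, which compares a list with all other genes, using a preset correlation of 0.01 and again with a correlation estimated from the residuals. A camera call below rests on the preset correlation unless said otherwise. The remaining list, erythroid cells and platelets, had fewer than 5 tested genes and was not tested. Members were counted as risen or fallen with p-values adjusted over all genes and adjusted over the list alone. limma's fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, called 19, 0, 20, 2 and 19 lists in the 5 comparisons. 3 further lists (HIF targets, pigment cell genes and the MYC network) were chosen after the results were seen.

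The rule for the genes named in the text was also fixed before the data were examined. Tfeb, Esr1, Myc, Tfe3, Mitf and Tfec were always named. For 4-OHT in TFEB cells and for the interaction, the 10 largest rises and 10 largest falls were taken, and for the other comparisons 5 of each. These had to pass the threshold, have a mean of at least 100 normalized counts, have groups that did not overlap and not be predicted genes. For each list described, up to 4 members with the largest change past the threshold were eligible, or the member with the smallest p where none passed. Other genes are named as chosen after their values were seen. Where both groups had reads but the lower one was near the floor, levels are given in place of a fold. Coordinates are those of GENCODE M21 on mm10.

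The analysis was tested on simulated read counts drawn from the real means and depths, with 200 changed genes in each of 5 sets per comparison. For 4-OHT in TFEB cells (12041 genes) it recovered 78.8% of 2-fold and 93.2% of 4-fold changes, and 5.08% of calls were false. For 4-OHT in vector cells (12046 genes) these shares were 78.6%, 92.0% and 4.80%, and for the interaction (12038 genes) 64.2%, 84.0% and 5.48%. Between the lines they were 74.8%, 92.0% and 5.44% in vehicle (12021 genes) and 76.6%, 90.8% and 5.53% in 4-OHT (12040 genes). With the 17 V-ATPase genes raised 1.5-fold, camera called that list (adjusted p = 6.47e-34) and 0 of the other 27 lists. The simulated genes varied independently of each other. This run therefore does not test how often camera with the preset correlation calls lists of correlated genes falsely. The changed genes were drawn only from genes above a minimum mean, so recovery among the lowest genes was not tested. Apart from those changes all simulated libraries had the same mean profile. Background that differs between libraries was thus not simulated, and the share of false calls may not hold for the real libraries.

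The alternatives tried were pseudocounts of 0.5 and 10, no filter and a minimum of 50, TMM and upper-quartile scaling, quantile normalization, fitting only the groups compared, no variance trend, array weights, the replicate number as a block, edgeR, DESeq2, and leaving out each library in turn. An alternative without 3 libraries, the one with the most genes with reads in each group except vector cells in vehicle (19057, 16471 and 19250 genes), was chosen after seeing the data. Since the strand setting is unknown, reads of overlapping genes cannot be separated. Among the genes named, Atf5, Atg9b, B3gnt8, Gins2, Nusap1, Pdha1, Pmel, Rag1, Rag2, Sgsh, Shmt2, Slc15a3, Slc6a9, Tk1, Tmem255a and Yars share exonic positions with another gene, and their values are uncertain to that extent. Gp49a and Lilrb4 are near-identical neighbors whose reads counting could divide either way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw reads were not analysed here.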

Results

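The data are normalized read counts of genes in 12 RNA-seq libraries of a Myc-driven mouse B cell lymphoma kept in culture with interleukin-7. Vector cells carried an empty retrovirus and TFEB cells carried the TFEB-ERT2 fusion, and each line was given vehicle or 4-OHT, with 3 libraries per group. Total reads per library ran from 11849029 to 22109283. The number of genes with any read varied more within groups than between them, from 11390 to 19250. It averaged 13180 ± 2001 (SD, n = 3) in vector cells in vehicle, 14520 ± 3948 in vector cells in 4-OHT, 14790 ± 2364 in TFEB cells in vehicle and 16010 ± 3556 in TFEB cells in 4-OHT. All values after ± below are SDs over the 3 libraries of a group, in normalized counts. The share of reads from Rn45s, the ribosomal RNA precursor, was 6.31 ± 0.73% and 5.35 ± 0.51% in vector cells without and with 4-OHT, and 5.67 ± 0.95% and 4.37 ± 0.21% in TFEB cells. In TFEB cells the 3 libraries in 4-OHT all lay below the 3 in vehicle. The exact two-sided permutation p of that difference was 0.1, the smallest that groups of 3 allow, and in vector cells it was 0.2. In a principal component analysis of the 7794 genes with a mean of at least 200, the first component held 65.3% of the variance and the second 14.5%, and over all 13111 tested genes they held 42.6% and 16.3%. Over the 7794 genes the first component set TFEB cells in 4-OHT (45.7 to 46.6) apart from all other libraries (-19 to -9). Over all tested genes it split libraries of the same group. Vector 4-OHT library 2 stood at 94.4 against -56.6 and -77, and TFEB vehicle library 3 at 99.1 against 15.3 and -56.9.

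**Figure D1:**
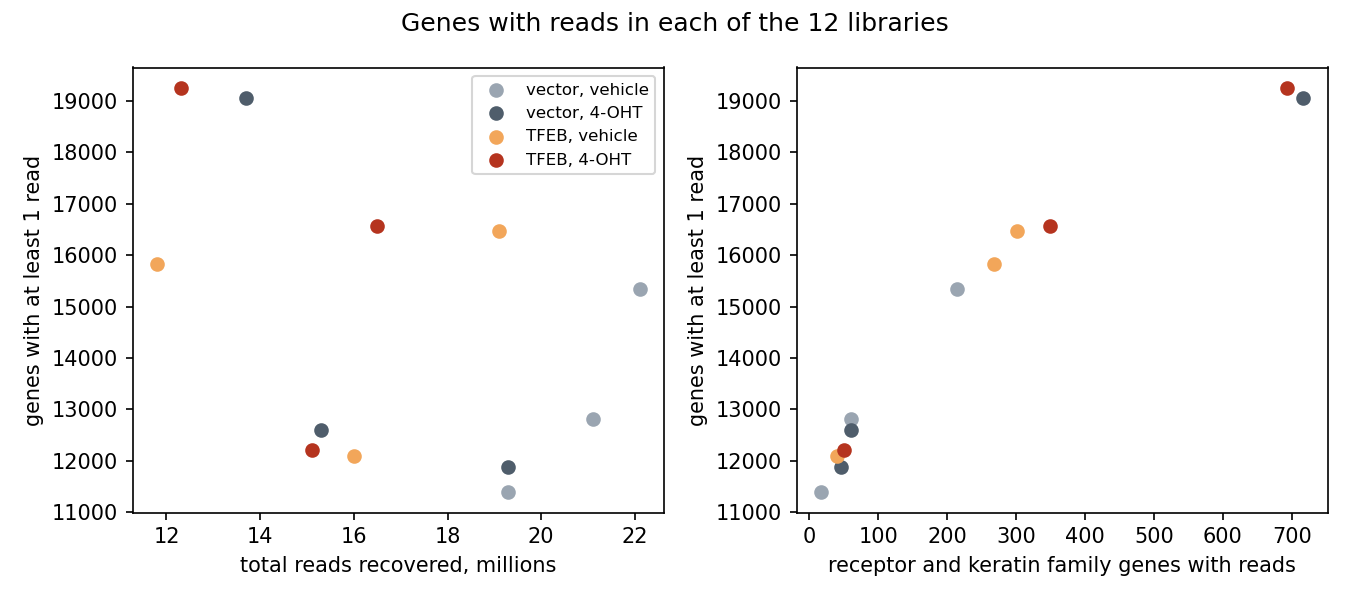
Number of genes with at least 1 read in each of the 12 libraries, against the library's total reads (left) and against the number of its normally silent receptor, keratin and beta-defensin family genes with reads (right). Genes with reads range from 11390 to 19250 and are spread within every group.

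Tfeb itself, measured by reads assigned to the mouse gene (17:47737030-47792419, mm10), checks the labels. Vector cells had 243 ± 17.7 in vehicle and 221 ± 23.4 in 4-OHT. TFEB cells had 1676 ± 249 in vehicle, 6.83-fold more than vector cells (log2 2.77 ± 0.15 SE, adjusted p = 2.8e-14, limma), and 665 ± 72.6 in 4-OHT, 2.99-fold more (log2 1.58 ± 0.15 SE, adjusted p = 7e-10, limma). Within TFEB cells, Tfeb therefore fell 2.51-fold with 4-OHT (adjusted p = 2.49e-08, limma), and this change differed from that in vector cells (interaction log2 -1.19 ± 0.21 SE, adjusted p = 0.000113, limma). Whether the fusion was built from the mouse or the human gene is not given in the sources used here, so these reads cannot be divided between the transgene and the endogenous gene. Esr1, the mouse gene of the receptor from which the fusion domain derives in its human form, fell 2.42-fold in TFEB cells, from 228 ± 62.1 to 91.1 ± 7.54 (adjusted p = 0.000617, limma). Its levels in vector cells were 185 ± 24.1 and 124 ± 14.2, and the interaction did not pass (log2 -0.71 ± 0.39 SE, adjusted p = 0.272, limma). Of the close relatives of Tfeb, Mitf had mean levels from 27.9 to 45.3 in the 4 groups. Tfe3 and Tfec were at 0 in most libraries, with highest group means of 7.83 ± 13.6 for Tfe3 and a highest library value of 14.2 for Tfec.

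The comparison of 4-OHT with vehicle in TFEB cells asks what the activated fusion protein does to expression. Camera called lysosomal hydrolase, lysosomal membrane and V-ATPase genes higher and B cell precursor genes lower, also with an estimated correlation. It called unfolded protein response genes higher and cell cycle, glycolysis, ATF4 and tRNA synthetase genes lower with the preset correlation only (adjusted p = 0.1, 0.1, 0.115, 0.105 and 0.1 with an estimated one). Legumain (Lgmn), a lysosomal protease, rose 7.15-fold from 1216 ± 159 to 8654 ± 75.1, and Mtor, the kinase of mTORC1, rose 3.96-fold from 6501 ± 256 to 25720 ± 637. Il33, an alarmin cytokine, fell 40.8-fold from 5648 ± 167 to 141 ± 38.0, and Rag1, a recombinase of antigen receptor genes, fell 13.6-fold from 1265 ± 126 to 94.6 ± 26.9. In all, 3611 of 13111 genes passed the threshold in limma, 1792 higher and 1819 lower in 4-OHT. Of these, 1049 changed at least 2-fold, 558 up and 491 down. The median log2 change over all tested genes was 0.035.

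Several of the largest rises came from genes with no or almost no reads in vehicle. Fam46c (3:100451628-100489324, mm10), a poly(A) polymerase, was at 0 in all 3 vehicle libraries and reached 3220 ± 169 in 4-OHT, at least 777-fold above the floor of 3 reads per library (adjusted p = 1.68e-11, limma). Ccl3 (11:83647844-83649355), a chemokine, was also at 0 and reached 1645 ± 142, at least 397-fold higher (adjusted p = 3.24e-09, limma). Angptl2 (2:33216069-33247717), a secreted angiopoietin-like protein, went from 3.23 ± 5.59 to 1225 ± 86.3. Mylk4, a myosin light chain kinase, went from 15.8 ± 22.4 to 1823 ± 258, and Spp1, which encodes osteopontin, from 6.84 ± 5.48 to 882 ± 70.8. The cation channel gene Trpm1 went from 4.15 ± 7.18 to 650 ± 21.9. The paralogous inhibitory receptor genes Lilrb4 and Gp49a went from 7.07 ± 7.66 to 1320 ± 370 and from 0.286 ± 0.495 to 577 ± 140, although reads of this near-identical pair may have been exchanged between them. Hpgds, a prostaglandin D synthase, reached 553 ± 79.9 from 8.28 ± 9.07, and Cd28, a T cell costimulatory receptor, 402 ± 28.8 from 6.96 ± 8.61.

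Large falls included regulators and surface or secreted proteins. Heyl, a Notch-responsive repressor, fell from 196 ± 36.1 to 2.91 ± 4.22. Tgfb3 (12:86056745-86079041), a TGF-beta ligand, fell 36.6-fold from 1203 ± 87.4, and Sertad4 fell 30.1-fold from 1088 ± 239. Tgfb3 was also called lower with 4-OHT in vector cells, as given below, but there its groups overlapped and several alternatives lost the call. Whether its fall was particular to TFEB cells therefore stays open. Blk, a Src-family kinase of B cells, fell from 139 ± 52.6 to 8.51 ± 7.37, and Tmem255a from 248 ± 13.8 to 11.6 ± 3.12. Acot1, an acyl-CoA thioesterase, fell from 247 ± 69.7 to 10.3 ± 11.8, B3gnt8, a glycosyltransferase, from 236 ± 73.9 to 9.15 ± 7.65, and Umod from 96.3 to 5.31 ± 2.52. In all 20 of these genes the 3 libraries in 4-OHT lay on 1 side of the 3 in vehicle, as the rule for naming them required. Their calls held under the alternatives tried.

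**Figure D2:**
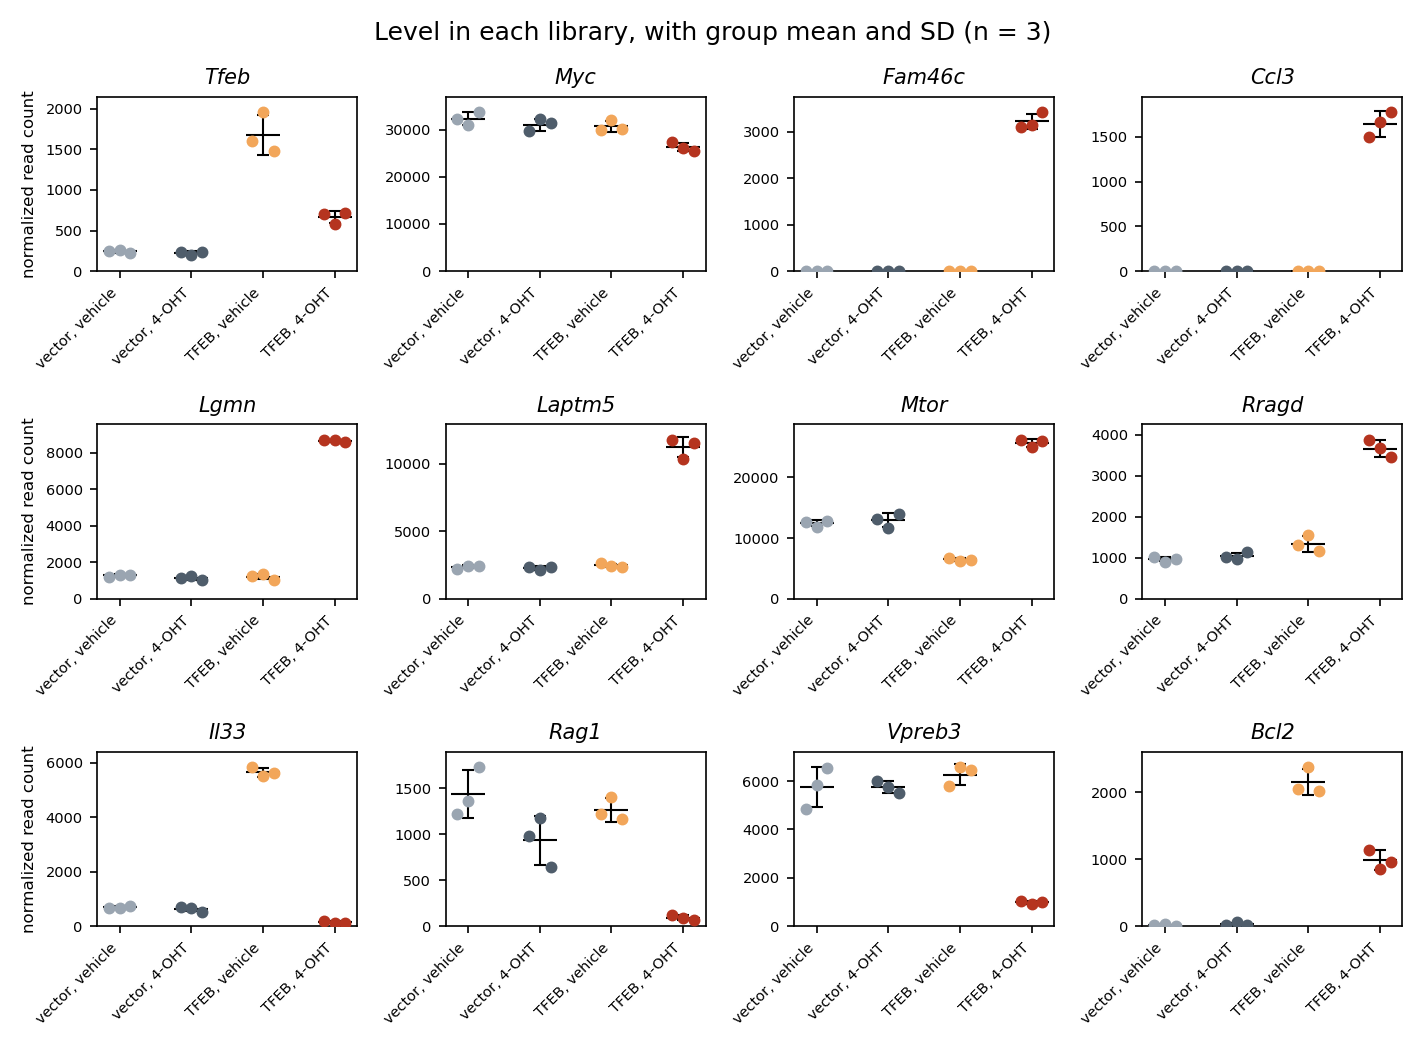
Normalized counts of 12 genes in each library of the 4 groups, with a point per library, lines for group means and bars for SDs (n = 3). Tfeb is highest in TFEB cells in vehicle (1676 ± 249) and Lgmn in TFEB cells in 4-OHT (8654 ± 75.1).

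Of 50 lysosomal hydrolase genes, 28 rose and 1 fell with p-values adjusted over all genes, and 30 and 1 adjusted over the list alone. Besides Lgmn they included the sulfatases Sgsh (6.54-fold) and Galns (5.80-fold) and the peptidase Dpp7 (4.69-fold). Their median log2 change was 0.74 (camera adjusted p = 1.41e-14). Of 32 lysosomal membrane genes, 16 rose and 0 fell on both counts (16 and 0 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 4.6e-06). Among them, Laptm5 rose 4.55-fold to 11220 ± 748, the peptide transporter Slc15a3 went from 25.4 ± 10.3 to 551 ± 126, and Gpnmb from 5.27 ± 5.15 to 246 ± 44.7. Cd68, a lysosomal glycoprotein also used as a macrophage marker, rose 2.52-fold (limma adjusted p = 0.00574), a call lost without 3 libraries, the one with the most genes with reads in each group except vector cells in vehicle (adjusted p = 0.0509, over a range of 9.98e-05 to 0.0509 in all alternatives). Of 17 V-ATPase genes, which encode the proton pump that acidifies lysosomes, 10 rose and 0 fell, or 13 and 0 adjusted over the list alone. Atp6v0a1 (2.26-fold), Atp6ap2 (2.20-fold), Atp6v1b2 (2.08-fold) and Atp6v1a (1.82-fold) rose most, and the list's median was 0.72 (camera adjusted p = 7.88e-07). Of the 15 lists that camera called here, 6 higher and 9 lower, these 3 and the B cell precursor list held with an estimated correlation, with adjusted p = 0.00173, 0.00606, 0.00606 and 0.0388.

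Autophagy and mTORC1 genes moved in both directions. Of 50 autophagy genes, 18 rose and 4 fell (19 and 5 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.0119. With an estimated correlation the adjusted p was 0.115. The receptor Optn rose 7.42-fold, Tecpr1 rose 2.67-fold and Atg7 rose 1.94-fold, whereas Atg9b fell 2.47-fold. Of 40 genes of mTORC1, the Rag GTPases and amino acid sensing, 12 rose and 7 fell (13 and 7 adjusted over the list alone), and the list was not called (median 0.03, camera adjusted p = 0.332). Besides Mtor, Rragd, a Rag GTPase, rose 2.76-fold and Fnip1, a folliculin partner, rose 2.24-fold. Fnip2, at 3.35 ± 3.43 in vehicle and 45.4 ± 29.8 in 4-OHT, had an adjusted p of 0.0497 in limma. Its call was lost without TFEB vehicle library 2 (adjusted p = 0.0746) or 3 (0.158) and without TFEB 4-OHT library 1 (0.0692), 2 (0.166) or 3 (0.122), and over all alternatives it ranged from 0.00868 to 0.207.

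**Figure D3:**
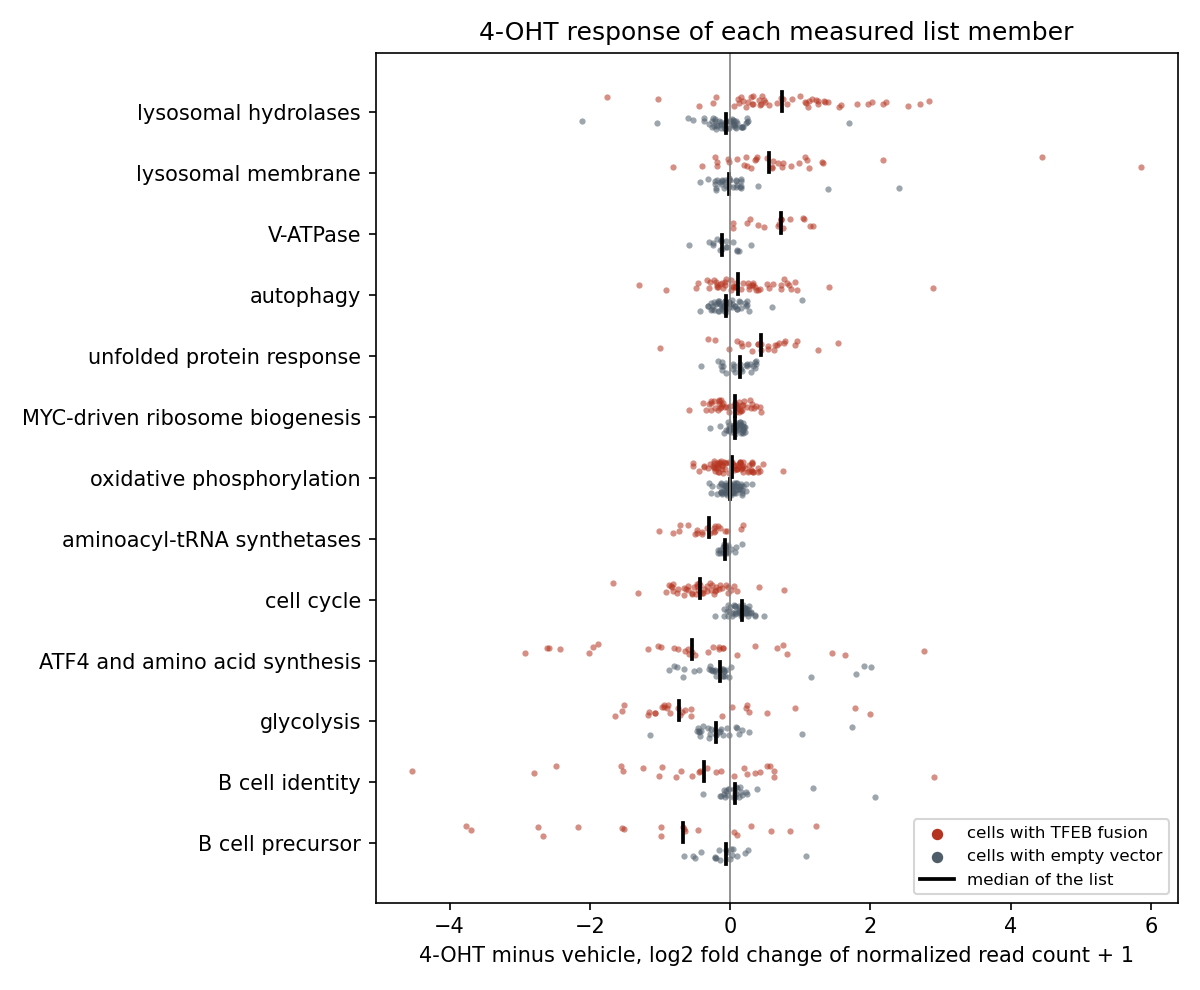
Log2 change with 4-OHT of each measured member of 13 gene lists in TFEB cells and in vector cells, with the median of each list as a line. Lysosomal hydrolases stand at 0.74 in TFEB cells and at -0.05 in vector cells.

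Of 31 genes of the ATF4 response and amino acid synthesis, 17 fell and 3 rose, also when adjusted over the list alone (17 and 3), with a median of -0.55 (camera adjusted p = 1.34e-06). With an estimated correlation the adjusted p was 0.105. Trib3, a stress-induced pseudokinase, fell 7.62-fold, Cth, which makes cysteine, 6.10-fold and Chac1, which degrades glutathione, 5.97-fold, while the transcription factor Atf5 rose 6.79-fold. Of 22 aminoacyl-tRNA synthetase genes, 12 fell and 0 rose (15 and 0 adjusted over the list alone), including Cars (2.02-fold), Yars (1.76-fold), Gars (1.65-fold) and Vars (1.64-fold). Their median was -0.30 (camera adjusted p = 2.17e-06, and adjusted p = 0.1 with an estimated correlation). Of 23 amino acid transporter genes, 3 rose and 7 fell (4 and 7 adjusted over the list alone). The neutral amino acid transporter Slc1a4 fell 3.51-fold, the glycine transporter Slc6a9 3.09-fold and Slc43a1 2.14-fold, the glutamine transporter Slc1a5 rose 1.92-fold, and the list was not called (median -0.13, camera adjusted p = 0.645).

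Energy and biosynthetic genes changed as follows. Of 28 glycolysis genes, 17 fell and 2 rose on both counts (17 and 2 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 4.95e-07, and adjusted p = 0.115 with an estimated correlation). Aldoc fell 3.10-fold, Pgk1 2.90-fold and Pdk1, which restrains pyruvate dehydrogenase, 2.85-fold, whereas Eno3, the muscle enolase, rose 3.44-fold. Of 34 nucleotide synthesis genes, 15 fell and 4 rose (16 and 5 adjusted over the list alone), among them Dck (2.27-fold), Impdh1 (1.98-fold) and Tk1 (1.96-fold) down and Adssl1 (5.96-fold) up. The list's median was -0.25 (camera adjusted p = 0.00233, and adjusted p = 0.115 with an estimated correlation). Of 33 sterol and fatty acid synthesis genes, 14 fell and 5 rose (16 and 5 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.00233, and adjusted p = 0.1 with an estimated correlation). Insig1, which restrains SREBP, rose 2.09-fold, Idi1 rose 1.87-fold and Ebp 1.79-fold, and Fdps fell 1.86-fold. The TCA cycle list (26 genes, 6 up and 3 down, or 6 and 5 adjusted over the list alone) had a median of 0.05 and a mean of -0.02 and was not called (camera adjusted p = 0.877). In it Pcx fell 2.27-fold and Idh2 1.64-fold, and Pdha1 rose 1.36-fold. The oxidative phosphorylation list (71 genes, 11 up and 5 down, or 10 and 5 adjusted over the list alone) had a median of 0.03 (camera adjusted p = 0.804), with Uqcr10 up 1.69-fold. Of 21 fatty acid oxidation genes, 3 rose and 2 fell on both counts (3 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.509). Ppargc1a, which encodes the coactivator PGC-1 alpha, went from 14.5 ± 7.06 to 860 ± 71.4, and Acadm rose 3.14-fold.

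Myc messenger RNA, whose reads are not divided here between the transgene and the endogenous gene, was 30650 ± 1249 in vehicle and 26350 ± 894 in 4-OHT (log2 -0.22 ± 0.08 SE, adjusted p = 0.052, limma), and did not pass. It passed with edgeR (adjusted p = 0.00993), DESeq2 (0.00288), array weights (0.0174), a minimum of 50 (0.0297), upper-quartile scaling (0.0334), only the groups compared (0.0374), a pseudocount of 10 (0.0426) and no variance trend (0.0486). Over all alternatives the adjusted p ran from 0.00288 to 0.672. Of 45 ribosome biogenesis genes known as MYC targets, 7 rose and 6 fell, also when adjusted over the list alone (7 and 6), and the list was not called (median 0.07, camera adjusted p = 0.981). Npm1, a nucleolar chaperone, fell 1.51-fold from 53430 ± 5876. Of 39 other MYC targets, 12 fell and 4 rose (13 and 5 adjusted over the list alone), with a median of -0.12. The camera call (adjusted p = 0.0336) was lost with an estimated correlation (adjusted p = 0.402) and with a minimum value of 50 (adjusted p = 0.0785), over a range of 0.00295 to 0.402. Bcat1, an aminotransferase of branched-chain amino acids, fell 4.03-fold, the transferrin receptor gene Tfrc 1.91-fold, Ldha, which makes lactate, 1.81-fold and Shmt2, a mitochondrial serine enzyme, 1.62-fold.

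Of 48 cell cycle genes, 30 fell and 1 rose, or 35 and 2 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 4.83e-11, and adjusted p = 0.1 with an estimated correlation). E2f2 fell 3.18-fold, Gins2 2.47-fold, Aurkb 1.88-fold and Nusap1 1.83-fold. Of 25 genes of the unfolded protein response, 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 4.95e-07, and adjusted p = 0.1 with an estimated correlation). Xbp1 rose 2.90-fold to 10790 ± 231, Edem1 2.38-fold and the chaperone gene Calr 1.94-fold, while Derl3 fell 2.00-fold. Among 27 p53 targets and apoptosis genes, 8 rose and 6 fell (10 and 6 adjusted over the list alone). That list had a median of 0.15 and was not called (camera adjusted p = 0.804), and fry gave it the opposite, downward, sign. In it the antiapoptotic gene Bcl2l1 fell 6.77-fold from 1294 ± 89.6, the proapoptotic gene Bmf fell 3.51-fold, and Plk2 went from 9.12 ± 8.60 to 502 ± 33.2. Bcl2 was at 2149 ± 195 in vehicle and 983 ± 149 in 4-OHT (log2 -1.13 ± 0.40 SE, adjusted p = 0.0308, limma). Its call was lost without TFEB vehicle library 1 (adjusted p = 0.0754), 2 (0.106) or 3 (0.0657) and without TFEB 4-OHT library 1 (0.0541), 2 (0.109) or 3 (0.0909), over a range of 1.06e-07 to 0.214 in all alternatives. The SE pools the spread of all 4 groups, and Bcl2 was low in vector cells in vehicle, as given below. The call held with only the groups compared, and was lost with DESeq2 (adjusted p = 0.114) and in limma without the variance trend (0.214).

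Genes of the B lineage fell more often than they rose. Of 26 B cell identity genes, 14 fell and 7 rose, or 15 and 8 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.00323, and adjusted p = 0.0606 with an estimated correlation). Besides Blk, Siglecg, an inhibitory lectin, fell 5.57-fold and the transcription factor Ikzf3 2.93-fold. Bank1, at 51.7 ± 5.39 in vehicle and 13.6 ± 12.7 in 4-OHT, passed in limma (adjusted p = 0.023) but lost the call without TFEB vehicle library 1 (adjusted p = 0.069) or 3 (0.0524) and without TFEB 4-OHT library 1 (0.247), over a range of 0.0048 to 0.247. Of 19 B cell precursor genes, 11 fell and 4 rose, or 12 and 4 adjusted over the list alone, with a median of -0.68 (camera adjusted p = 4.6e-06). Rag2 fell 12.9-fold, Erg 6.70-fold and Vpreb3, of the surrogate light chain family, 6.35-fold. Of 13 plasma cell genes, 5 rose and 2 fell on both counts (5 and 2 adjusted over the list alone). Cd28 and Xbp1 rose, Cd38 fell 2.87-fold and Slamf7 2.27-fold, and the list was not called (median 0.09, camera adjusted p = 0.288). Of 23 antigen presentation genes, 9 rose and 5 fell on both counts (9 and 5 adjusted over the list alone; median 0.36, camera adjusted p = 0.482). Of 25 interferon response genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.49, camera adjusted p = 0.227), with the RNA sensor gene Ifih1 going from 8.90 ± 9.08 to 156 ± 16.7.

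Markers of other cell types were mostly low. Of 11 T and NK cell genes, 5 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 1.27. The camera call (adjusted p = 0.0308) was lost with an estimated correlation (adjusted p = 0.353) and without the filter (adjusted p = 0.0724), over a range of 0.00758 to 0.353. Besides Cd28, the perforin gene Prf1 rose 5.40-fold, the adaptor gene Lat 2.42-fold and Cd2 1.86-fold. Of 7 macrophage and granulocyte genes, 0 rose and 1, Mrc1, fell 4.23-fold (0 and 1 adjusted over the list alone). That list had a median of 0.61 while camera gave it the downward sign (adjusted p = 0.992). Of 16 fibroblast and stroma genes, 0 rose and 1, Vim, fell 1.69-fold (0 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.992). Of 9 endothelial genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.11, a mean of -0.04 and a downward camera sign (adjusted p = 0.804). The endothelial gene with the smallest p, Pecam1, was at 805 ± 78.5 in vehicle and 684 ± 59.7 in 4-OHT (adjusted p = 0.161, limma). Over these libraries the share of reads from Rn45s was lower with 4-OHT, as given above.

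Vector cells show what 4-OHT does without the fusion protein. In limma 2 of 13111 genes passed, both lower in 4-OHT, and 822 had an unadjusted p under 0.05. edgeR called 0 genes (1009 under 0.05 unadjusted) and DESeq2 48 (1241 under 0.05 unadjusted). The tetraspanin gene Tspan13 (12:36014557-36042500, mm10) fell 1.71-fold, from 4056 ± 648 to 2421 ± 717 (log2 -0.77 ± 0.14 SE, adjusted p = 0.035, limma). Tgfb3, chosen after its values were seen because its groups overlapped, had 1311 ± 468 in vehicle and 286 ± 462 in 4-OHT (adjusted p = 0.035, limma). In 4-OHT its libraries stood at 26.8, 820 and 12.7. Neither gene kept its call with edgeR, DESeq2, a pseudocount of 0.5, a minimum of 50 or no variance trend. The count became 25 without vector vehicle library 1 and 55 without vector 4-OHT library 2, and 0 without vector vehicle library 2 or 3 or vector 4-OHT library 1 or 3. In those last 4 fits Tspan13 had adjusted p-values of 0.45, 0.553, 0.325 and 0.415, and over all alternatives it ran from 0.000205 to 0.929.

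No member of any of the 28 lists passed the threshold in vector cells, although camera called 7 lists. Cell cycle genes had a median of 0.16 (camera adjusted p = 4.08e-09), unfolded protein response genes 0.14 (0.000191, with 6 members higher and 0 lower adjusted over the list alone) and ribosome biogenesis genes 0.07 (0.00282). Glycolysis genes had a median of -0.20 (camera adjusted p = 8.86e-07, with 7 members lower and 0 higher adjusted over the list alone), ATF4 and amino acid synthesis genes -0.14 (9.61e-07), B cell precursor genes -0.05 (0.0057) and tRNA synthetase genes -0.07 (0.0349). Adjusted over the list alone, 0 members of the cell cycle, ribosome biogenesis and tRNA synthetase lists passed, 1 ATF4 gene was lower and 3 B cell precursor genes were lower. With an estimated correlation 0 of the 28 lists were called, and the smallest adjusted p was 0.34. Lysosomal hydrolase genes had a median of -0.05 (camera adjusted p = 0.0779).

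The interaction tests whether the response to 4-OHT differed between the 2 lines. It did for 2066 genes in limma, 1016 with a more positive response in TFEB cells and 1050 with a more negative one, and 780 of these differed at least 2-fold, 444 up and 336 down. Fam46c, Ccl3, Angptl2, Gp49a, Mylk4, Lilrb4, Trpm1 and Hpgds were again among the 10 with the most positive difference. The other 2 were Pmel (10:128704195-128720238, mm10), a melanosome matrix protein gene, and Tcf7, a transcription factor gene of T cells. Mylk4, Lilrb4, Trpm1 and Hpgds lost their interaction calls with edgeR, DESeq2 or both, as given in the closing section. Pmel had 43.2 ± 8.13 and 12.6 ± 20.9 in vector cells without and with 4-OHT, and 17.6 ± 7.12 and 982 ± 103 in TFEB cells (adjusted p = 1.71e-07, limma). Tcf7 had 15.7 and 8.32 in vector cells, and 17.5 ± 7.97 and 1309 ± 158 in TFEB cells (adjusted p = 1.78e-08, limma). The most negative difference was that of Il33, at 694 ± 52.3 and 636 ± 85.4 in vector cells against 5648 ± 167 and 141 ± 38.0 in TFEB cells (log2 -5.22 ± 0.20 SE, adjusted p = 4.51e-18, limma). Id3, an inhibitor of helix-loop-helix factors, differed by log2 -3.56 ± 0.25 SE, with 810 and 824 in vector cells and 767 ± 74.1 and 67.4 ± 21.2 in TFEB cells. Sema5b, a semaphorin gene, differed by -3.52 ± 0.22 SE. The response of Mtor also differed (log2 1.93 ± 0.11 SE, adjusted p = 3.77e-14, limma), with 12440 ± 520 and 12950 ± 1139 in vector cells, while that of Myc did not pass (-0.16 ± 0.12 SE, adjusted p = 0.456).

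Camera called 15 lists in the interaction, and 4 of them held with an estimated correlation. Lysosomal hydrolases responded more positively in TFEB cells, with 29 of 50 members up and 1 down, also when adjusted over the list alone (29 and 1), and a median of 0.85 (camera adjusted p = 1.82e-17, and adjusted p = 0.000899 with an estimated correlation). Lysosomal membrane genes (11 of 32 up and 0 down, or 13 and 0 adjusted over the list alone, median 0.60) and V-ATPase genes (9 of 17 up and 0 down, or 10 and 0 adjusted over the list alone, median 0.74) had adjusted p = 0.00443 each with an estimated correlation. B cell identity genes (4 of 26 up and 11 down, or 6 and 12 adjusted over the list alone, median -0.43) responded more negatively, with adjusted p = 0.0343 with an estimated correlation. B cell precursor genes (3 up and 10 down of 19, or 4 and 10 adjusted over the list alone, median -0.76) were called with the preset correlation (adjusted p = 6.73e-05) and not with an estimated one (adjusted p = 0.051). The same held for cell cycle genes, of which 0 were up and 26 down (0 and 35 adjusted over the list alone), with a median of -0.49, adjusted p = 2.09e-16 and then 0.0614 with an estimated correlation. Of the lists of other cell types, T and NK cell genes were called, with 5 of 11 members up and 0 down, also adjusted over the list alone (5 and 0), and a median of 1.24 (camera adjusted p = 0.0317). That call was lost with an estimated correlation (adjusted p = 0.321) and without the filter (adjusted p = 0.12), over a range of 0.00854 to 0.321. In the macrophage list 0 members were up and 1 down, and in the fibroblast and endothelium lists 0 of either, also adjusted over the list alone (0 and 1, 0 and 0, 0 and 0).

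In vehicle the 2 lines differed at 705 genes in limma, 379 higher and 326 lower in TFEB cells, 246 of them at least 2-fold (132 up and 114 down). Bcl2 (1:106538178-106714274, mm10), the antiapoptotic gene, was at 20.2 ± 16.8 in vector cells and 2149 ± 195 in TFEB cells (adjusted p = 7.17e-14, limma). Enpp3 was at 20 and 407 ± 47.9, Gabarapl1, an autophagy gene, at 15.1 and 222 ± 15.2, Itgb3, an integrin gene, at 5.16 and 103 ± 6.88, and Fndc1 was 13.1-fold higher at 452 ± 76.7. Cpeb1 was at 229 in vector cells and 1.14 ± 1.98 in TFEB cells, Rbms1 at 705 and 11.2 ± 13.9, Armcx4 at 1856 and 43.7 ± 31.5, Lrrk1 at 198 and 8.08 ± 7.41, and Trps1 at 529 and 17.6 ± 4.92. Il33 was also higher in TFEB cells in vehicle, 5648 ± 167 against 694 ± 52.3 (adjusted p = 1.25e-15, limma), and Mtor was lower, 6501 ± 256 against 12440 ± 520 (adjusted p = 9.92e-10, limma). Itgb3 and Lrrk1 lost their calls without the variance trend (adjusted p = 0.109 and 0.13, the highest of ranges that start at 4.85e-06 and 1.36e-06). The count was 439 without vector vehicle library 2, 433 without vector vehicle library 3 and 466 without TFEB vehicle library 2.

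Of the 28 lists, camera called 10 between the lines in vehicle, 2 higher and 8 lower in TFEB cells, and none with an estimated correlation (smallest adjusted p = 0.181). MYC-driven ribosome biogenesis genes had 0 higher and 3 lower, also adjusted over the list alone (0 and 3), with a median of -0.15 (camera adjusted p = 1.13e-06, and adjusted p = 0.481 with an estimated correlation). Other MYC targets had 0 higher and 5 lower (0 and 7 adjusted over the list alone, median -0.13, camera adjusted p = 2.41e-05, and adjusted p = 0.274 with an estimated correlation). Glycolysis genes were higher in TFEB cells in vehicle, with 3 members higher and 1 lower (9 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.0137, and adjusted p = 0.659 with an estimated correlation). Camera also called the ATF4 list (median -0.13, adjusted p = 0.0479), tRNA synthetases (-0.09, 0.0209), nucleotide synthesis (-0.08, 0.0251) and cell cycle (-0.08, 0.0225) lower. In the ATF4 list 0 members were higher and 3 lower, also adjusted over the list alone (0 and 3), and in the other 3 lists 0 members passed, also adjusted over the list alone (0 and 0). With a minimum of 50 these 4 calls were lost (adjusted p = 0.0851, 0.0851, 0.104 and 0.104). Over their alternatives these 4 ranged from 0.00531 to 0.715, 0.00132 to 0.643, 0.003 to 0.481 and 0.000966 to 0.796. Sterol and fatty acid synthesis genes had 4 members higher and 0 lower (6 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.000875, and adjusted p = 0.181 with an estimated correlation). Lysosomal hydrolases had 1 higher and 5 lower (1 and 6 adjusted over the list alone, median -0.07, camera adjusted p = 0.0165), a call lost with an estimated correlation (adjusted p = 0.238) and with a minimum of 50 (adjusted p = 0.104), over a range of 0.003 to 0.238. B cell identity genes had 0 higher and 7 lower (1 and 8 adjusted over the list alone, median -0.09, camera adjusted p = 0.00283, and adjusted p = 0.181 with an estimated correlation). Of the endothelial markers, Plvap was at 4.56 in vector cells and 129 in TFEB cells (adjusted p = 0.00041, limma), and 2 of 9 were higher and 0 lower, also adjusted over the list alone (2 and 0, camera adjusted p = 0.0784). Of the macrophage and granulocyte list and the fibroblast and stroma list, 0 members passed, also adjusted over the list alone (0 and 0). These lists had medians of 1.42 and 1.35 and the endothelial list 1.71. Neither of the first 2 was called (camera adjusted p = 0.637 and 0.339).

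With both lines in 4-OHT, 3553 genes differed in limma, 1785 higher and 1768 lower in TFEB cells, of which 1092 differed at least 2-fold (676 up and 416 down). This comparison holds both the effect of the activated fusion and differences between the lines that were present in vehicle. Ccl3, Fam46c, Lilrb4, Mylk4 and Gp49a were the 5 largest rises, with vector cells at 1.19, 4.41, 0.791, 6.72 and 0. Umod was at 236 in vector cells and 5.31 ± 2.52 in TFEB cells, Armcx4 was 32.4-fold lower, and Heyl, Blk and B3gnt8 were at 159, 249 and 322 in vector cells. Of 48 cell cycle genes, 41 were lower and 0 higher in TFEB cells (42 and 0 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 6.29e-22, and adjusted p = 0.0284 with an estimated correlation). Lysosomal hydrolases (34 of 50 higher and 2 lower, 36 and 2 adjusted over the list alone, median 0.83), lysosomal membrane genes (16 of 32 higher and 0 lower, 19 and 0 adjusted over the list alone) and V-ATPase genes (10 of 17 higher and 0 lower, 10 and 0 adjusted over the list alone) were called with an estimated correlation at adjusted p = 0.00292, 0.00505 and 0.0117. So were nucleotide synthesis genes (1 higher and 20 lower of 34, 2 and 21 adjusted over the list alone) and B cell identity genes (5 higher and 15 lower of 26, 5 and 15 adjusted over the list alone), at adjusted p = 0.0284 and 0.00782. Of the markers of other cell types, 6 of 11 T and NK cell genes were higher and 1 lower, also adjusted over the list alone (6 and 1), with a median of 1.67 (camera adjusted p = 0.0606). Of the pigment cell genes, a list chosen after the results were seen, 4 of 6 were higher and 0 lower, also adjusted over the list alone (4 and 0), with a median of 4.79 (camera adjusted p = 0.000436, and adjusted p = 0.223 with an estimated correlation). In the macrophage and granulocyte list 1 of 7 was higher and 1 lower (2 and 1 adjusted over the list alone), in the endothelium list 1 of 9 and 1 (1 and 0 adjusted over the list alone), and in the fibroblast list 0 of 16 and 0 (0 and 0 adjusted over the list alone). The other 8 of the 14 lists that camera called were lost. With an estimated correlation, adjusted p-values were 0.0678 for autophagy, other MYC targets and tRNA synthetases, 0.0575 for B cell precursor, 0.109 for ATF4, 0.15 for unfolded protein response and 0.362 for glycolysis genes. MYC-driven ribosome biogenesis genes (1 higher and 14 lower of 45, 1 and 17 adjusted over the list alone, median -0.22) had camera adjusted p = 3.61e-05, and adjusted p = 0.337 with an estimated correlation.

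Myc itself was 1.18-fold lower in TFEB cells than in vector cells in 4-OHT, 26350 ± 894 against 31050 ± 1267 (log2 -0.24 ± 0.08 SE, adjusted p = 0.0339, limma). The call was lost without vector 4-OHT library 2 (adjusted p = 0.113) or 3 (0.06), without TFEB 4-OHT library 1 (0.0569), 2 (0.108) or 3 (0.145), without the filter (0.105) and under TMM scaling (0.104) or quantile normalization (0.468), over a range of 0.0011 to 0.468.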

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

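The response to 4-OHT differed between the TFEB and vector lines, tested by the interaction in limma, for 2066 genes, the 20 named genes below and 15 of the 28 lists. The lists were called by camera with the preset correlation, and 4 of them held with an estimated one. Groups held 3 libraries each, too few to test single libraries against the others of their group. The log2 differences were largest for Fam46c (10.81), Ccl3 (10.72), Angptl2 (9.84), Gp49a (9.69), Pmel (9.15), Mylk4 (7.92), Lilrb4 (7.47), Trpm1 (7.18), Tcf7 (7.03) and Hpgds (6.96), most of them near the floor in vector cells. These values depend on the pseudocount, and with a pseudocount of 10 that of Fam46c was 8.01 and that of Hpgds 5.09. They also depend on the tool. edgeR gave 4.91 for Lilrb4 and 4.89 for Trpm1, lower than limma, and 7.81 for Hpgds, higher than limma. On the negative side were Il33 (-5.22), Heyl (-5.12), Acot1 (-5.10), Sertad4 (-4.53), B3gnt8 (-4.35), Blk (-4.16), Tmem255a (-3.84), Umod (-3.83), Id3 (-3.56) and Sema5b (-3.52). Of these 20, Mylk4 lost its call without the variance trend (adjusted p = 0.0525) and with DESeq2 (0.201), over a range of 2.62e-08 to 0.201. Blk lost it without the trend (0.0687, range 1.19e-11 to 0.0687) and Hpgds with edgeR (0.123, range 2.89e-07 to 0.123). Lilrb4 lost it with edgeR (0.965) and DESeq2 (0.137), over a range of 1.74e-09 to 0.965. Trpm1 lost it with edgeR (0.101), DESeq2 (0.536) and no trend (0.0698), over a range of 2.19e-06 to 0.536.

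The lists whose genes responded more positively in TFEB cells had median log2 differences of 0.85 (lysosomal hydrolases), 0.74 (V-ATPase), 0.60 (lysosomal membrane), 0.31 (unfolded protein response), 0.14 (autophagy) and 1.24 (T and NK cells). Those that responded more negatively had -0.76 (B cell precursor), -0.63 (glycolysis), -0.50 (ATF4 and amino acid synthesis), -0.49 (cell cycle), -0.43 (B cell identity), -0.33 (nucleotide synthesis), -0.31 (aminoacyl-tRNA synthetases), -0.26 (sterol and fatty acid synthesis) and -0.19 (other MYC targets). With an estimated correlation, the unfolded protein response (adjusted p = 0.192), autophagy (0.0807), T and NK cell (0.321), glycolysis (0.245), ATF4 (0.215), nucleotide (0.086), tRNA synthetase (0.189), sterol (0.172), other MYC target (0.304), cell cycle (0.0614) and B cell precursor (0.051) lists were not called.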

How the results depend on the processing

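Leaving out 1 library at a time gave 2975 to 3420 genes for 4-OHT in TFEB cells, 0 to 55 in vector cells, 1773 to 2108 for the interaction, 433 to 650 between the lines in vehicle and 2973 to 3334 in 4-OHT. The count of 2 in vector cells became 0 with a pseudocount of 0.5, a minimum of 50, quantile normalization, only the groups compared, no variance trend or edgeR, and 42 with array weights, 48 with DESeq2 and 11 without the library with the most genes with reads in each group except vector cells in vehicle (chosen after seeing the data). The 705 genes between the lines in vehicle became 352 with only the groups compared, 259 without the variance trend, 1125 with array weights and 1224 with DESeq2. With the replicate number as a block the 5 counts were 3601, 2, 2094, 723 and 3548. Correlations between libraries of the same number, after removing group means, ran from -0.52 to 0.67. They averaged 0.36 between the lines in 4-OHT, against -0.18 for libraries of different number. The averages for the same number were -0.2 within TFEB cells, -0.08 within vector cells and 0 between the lines in vehicle. A batch shared by number among the 4-OHT libraries therefore stays open. Without the filter the camera sign of 3 lists that were not called turned for 4-OHT in TFEB cells: ribosome biogenesis (median 0.07), TCA cycle (0.05) and macrophages (0.76). The cause was not tested. Fitting only the groups compared was not run for the interaction, which uses all 4 groups. Depth and 3 libraries per group limit what can be seen among low genes.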

Other observations

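Among the MYC network genes, chosen after the results were seen, Mxd1, which encodes an antagonist of MYC at shared DNA sites, rose 18.6-fold with 4-OHT in TFEB cells (log2 4.22 ± 0.15 SE, adjusted p = 1.06e-19, limma). Mnt, another antagonist, rose 1.56-fold (adjusted p = 4.94e-05, limma). Mxi1 and Mxd3, also antagonists, fell 2.49-fold (adjusted p = 1.15e-09, limma) and 2.74-fold (adjusted p = 0.0431, limma), so antagonists moved in both directions. Max did not change past the threshold (log2 0.03, adjusted p = 0.877, limma). Of the 11 network genes 3 rose and 3 fell (camera adjusted p = 0.673).

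The fall of glycolysis genes with 4-OHT in TFEB cells was followed up with tests chosen only after it was seen. As a hypothesis, lower HIF activity could lower these genes, and the test was whether HIF targets outside the glycolysis list also fell. Their median log2 change was -0.70, with 13 of 21 lower and 2 higher (camera adjusted p = 3.61e-07, and adjusted p = 0.159 with an estimated correlation). With 4-OHT in vector cells their median was -0.12 (camera adjusted p = 0.000158, and 0.301 with an estimated correlation). In the interaction it was -0.76 (camera adjusted p = 2.47e-05, and 0.278 with an estimated correlation), and between the lines in vehicle 0.21 (camera adjusted p = 0.105). Bnip3 fell 6.13-fold and Ankrd37 8.56-fold, while Vegfa stayed at log2 0.00 (adjusted p = 0.992). Lower MYC activity is the other hypothesis, and ribosome biogenesis genes, which MYC drives, had a median of 0.07 (bootstrap interval -0.11 to 0.11 over 10000 draws), a value already known when this test was set, which leaves it open.

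Whether other groupings of the same libraries call as many genes was tested by regrouping them. For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. Only 1 split, the real one, called as many genes for 4-OHT in TFEB cells (3611, highest other 0), between the lines in vehicle (705, highest other 0) and between the lines in 4-OHT (3553, highest other 0). In vector cells 2 splits of 10 reached the real 2 genes (highest other 2). The other splits mix libraries of both real groups. Where the groups differ, this widens the spread within them, so few calls were likely beforehand. For the interaction, 1 of 100 random splits, the real one, reached 2066, and the highest other was 1470. These splits also break up the differences between lines and treatments, so they do not test the interaction alone.

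Ccl3 and Lilrb4, known from myeloid cells, and Pmel and Trpm1, known from pigment cells, rose with 4-OHT in TFEB cells, and these tests were chosen only after that was seen. Of 7 macrophage and granulocyte genes 0 rose (camera adjusted p = 0.992). Of 6 pigment cell genes 3 rose and 0 fell, with a median of 3.65 (camera adjusted p = 0.0392, and adjusted p = 0.365 with an estimated correlation). If macrophages were the source, their markers would likely be high. However, 6 macrophage markers summed to 19.8 ± 20 in 4-OHT, 0.012 of the Ccl3 mean, and to 23.9 ± 33.5 in vehicle. Myeloid cells that lack these markers were not tested. For pigment cells, Tyr, Tyrp1, Dct and Mlana summed to 21.7 ± 18.4, 0.021 of the Pmel mean and at most 0.036 in any library. For 4-OHT itself, the median ratio of the vector to the TFEB log2 change over the 10 genes with the largest rises, which include Ccl3, Lilrb4 and Trpm1 but not Pmel, was 0.047, the largest 0.25. These 10 genes were picked for their rise in TFEB cells, which favors a small ratio. In vector cells in 4-OHT, Ccl3, Lilrb4, Pmel and Trpm1 stood at 1.19, 0.791, 12.6 and 11.9, against 1645, 1320, 982 and 650 in TFEB cells. The marker sums argue against macrophages as the source of Ccl3 and Lilrb4, and against pigment cells as the source of Pmel and Trpm1. The levels in vector cells argue against 4-OHT alone for these 4 genes. Whether the fusion acts on these genes directly stays open.

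The number of genes with reads differed between libraries, and the tests of depth, starting molecules and background were chosen only after that was seen. It did not follow depth (Spearman -0.43, permutation p = 0.162, Pearson -0.45, p = 0.145, and -0.55 without the 2 farthest libraries), and the share of its variance between groups was 0.14 (permutation p = 0.695). Few starting molecules copied into many reads could contribute, since in 10 of 12 libraries the most common read count among genes with 1 to 30 reads was above 1. A background of DNA-like reads could also contribute. It was followed by 1642 genes picked by symbol from normally silent families, namely chemosensory receptors, keratins and their associated proteins, and beta-defensins. The number of other genes with reads followed how many of these had reads (Spearman 0.98, Pearson 0.96, permutation p = 1e-05 for both, and Pearson 0.99 without the 2 farthest libraries). In the 3 libraries with the most genes, silent genes with reads had exons 1.09 to 1.17 times as long as those without. How much each of these adds stays open.

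Of the 705 genes that differed between the lines in vehicle, activity of the fusion without ligand could explain those that moved on in the same direction with ligand; the count of 86 was a test chosen only after the result was seen. The share whose interaction had the same sign was 0.3, below the 36.7 to 43.3% of 50 simulated sets without a ligand effect. The simulated genes varied independently, whereas real library differences can move many genes together, so that range may be too narrow. Of the 304 genes that also passed the interaction threshold, 218 did so in the opposite direction, a count without a simulated counterpart. Both comparisons use the vehicle libraries, with opposite sign, which favors opposite directions. Whether the set moved back with ligand therefore stays open. Ligand-free activity followed by an opposite effect of ligand would also give a low share, so this test cannot decide on the whole set. The other 86 of the 304 genes passed in the same direction. For these nothing here separates ligand-free activity from other effects of the ligand. Background reads in low genes could add calls, and the share of calls kept was 0.97 with a minimum of 50 and 0.71 without TFEB vehicle library 3. Without vector vehicle library 3, which had the fewest silent genes with reads, it was 0.59, and without TFEB vehicle library 2 it was 0.60. Leaving out a library therefore did not separate background from the loss of a replicate, and background stays open. Drift between the lines could not be tested with 1 line per insert.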
